A study of Danio rerio with 6 samples.

How the data were processed

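Trunk and tail muscle of zebrafish larvae, with the head, heart and gut removed, was profiled at 3 to 3.5 days after fertilization on the Affymetrix Zebrafish Genome Array, a short-oligonucleotide array with 1 biotin label per sample. Mutants of the runzel line were set against wildtype siblings, with 3 arrays per group and 6 in all. Per the labels' protocols, muscle RNA was pooled and prepared with Qiagen RNeasy or RNeasy Micro kits, and arrays were read on a GeneChip Scanner 3000 with default parameters in GeneChip Operating Software 1.2. The series description states that mutants were matched with siblings of the same clutch and that 3 clutches were used, but no label says that an array's replicate number marks a clutch.

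The deposited values are linear signal intensity, 1 value per probe set and array, as the values themselves show. Neither the summary method nor the scaling target is given in the sources used here. The 2% trimmed mean lay between 1500.42 and 1500.46 on all 6 arrays, so the table was already scaled and was kept as deposited. The deposited signal was analysed as log2 of the value plus 50, so that fold changes on this scale understate the change of dim probe sets. The number of arrays limits the precision of every value.

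The table held 15617 probe sets, of which 115 were manufacturer's controls and were left out of the tests. Of the other 15502 probe sets, 10795 had 1 gene symbol in the platform annotation, 135 had several and 4572 had none. An Entrez identifier was found in the RefSeq gene table for 10711 of them, and 1 symbol was replaced by the current one, giving 8793 distinct genes. No gene was named from a probe set with several symbols. Probe sets with a mean log2 value under the 40th percentile, a level of 8.904, were left out, which kept 9301 for testing.

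Groups were compared with limma 3.58.1 in R 4.3.3, by empirical Bayes with an intensity trend and Benjamini-Hochberg adjustment over the tested probe sets, at a threshold of 0.05. All tests are two-sided. The fit without a block was set as the primary one, and a fit with the replicate number as a block was set beside it. Whether the numbers pair the samples was checked before the calls of the fits were compared. Deviations from the group means correlated between arrays of the same number at 0.551, 0.389 and 0.526, and between arrays of different numbers at -0.401 to -0.152. The replicate numbers were therefore taken to pair the samples, from the data and not from a label. Deviations sum to 0 within a group, so positive values for the same number make those for different numbers negative on the whole. The negative values are thus not separate support. Adjusted p-values called paired come from the limma fit with this block and those called unpaired from the fit without it. For single probe sets an exact permutation test over the 10 splits was run, whose smallest p is 0.1, and an exact sign-flip test over the 3 pairs, whose smallest p is 0.25.

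Gene lists, 34 in all, were written before the data were examined, as were the comparison, the filter, the other settings to be tried and the rule for named genes. They cover titin, muscle structure, protein quality control, metabolism, stress, growth, and markers of tissues beside muscle or removed by dissection. Each gene was represented by its brightest tested probe set, giving 6136 genes. Lists with at least 5 tested genes, 30 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists. The lists of titin, slow-muscle sarcomere, heart muscle and eye and lens genes had too few tested genes. Camera with an estimated correlation and limma's fry were the alternatives. With an estimated correlation camera uses only 4 residual degrees of freedom, or 2 with the block. A call lost there therefore need not mean that the genes of a list vary together. Several lists share genes. Examples are unc45b and hsp90aa1.1 in the heat shock and the myogenic lists, and hspa1b in the heat shock and immediate-early lists. Further examples are socs3b in the inflammation and immediate-early lists, and trim55b in the M-band and ubiquitin ligase lists.

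The rule for named genes took every titin probe set and, per direction, the 12 largest changes among passing probe sets with 1 symbol and non-overlapping groups. Where fewer than 12 passed, it was filled by the smallest unadjusted p among probe sets with non-overlapping groups and an absolute log2 change of at least 1. It also took up to 4 members of each called list and up to 2 of every other list. Symbols that are only clone or locus names were passed over, 2 of them in the fill. Without the block, the fill gave 10 genes higher and 3 lower. The same rule applied to the paired fit, with the same sign in all 3 pairs in place of non-overlapping groups, was added after the data were seen and gave 12 genes in each direction, with 2 clone names passed over. Other genes named in the text were chosen after their values were seen.

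Other settings tried were pseudocounts of 16 and 200, quantile normalization, median centring, no filter, a filter at the 60th percentile, no intensity trend, robust empirical Bayes, omission of probe sets that can cross-hybridise, the mean of probe sets per gene, the replicate block, and each array left out in turn. Added after the data were seen were the replicate number as a random block, each pair left out, the other settings run in the paired fit, and lists without the genes they share with the heat shock list. The procedure was tested on simulated data with 9301 probe sets. Without the block it recovered 54 of 100 probe sets changed by a log2 of 1 and 97 of 100 changed by 2, with 0 false calls. With the block it recovered 97 and 100, with 7 false calls. The simulated values used block effects and variances of the paired fit, so these counts do not test the pairing or the intensity trend. In the list test, simulated on 6136 genes, a list of 30 genes moved by 0.5 was called in both fits, and 0 of 100 unmoved lists were called. Noise was drawn independently for each probe set, so these list counts do not test lists whose genes vary together.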

Results

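Signal was measured on 6 arrays, 3 of runzel mutants and 3 of wildtype siblings. The series description names 3 clutches, but no label ties an array's number to a clutch. Arrays of the same number were taken as pairs from the correlation of their values. Median signals lay between 602.1 and 672.3. Arrays of the same group correlated at 0.958 to 0.97 over probe sets, and arrays of the same number in different groups at 0.961 to 0.975. On the manufacturer's control probe sets, the ratio of 3′ to 5′ actin signal, a common reading of RNA integrity, was 2.49 ± 0.398 in runzel and 1.51 ± 0.195 in wildtype siblings (SD, n = 3, exact permutation p = 0.1, the smallest possible). The GAPDH ratio was 1.5 ± 0.0374 and 1.57 ± 0.0391 (exact permutation p = 0.2).

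The comparison asked which transcripts differ between runzel muscle and that of wildtype siblings when the phenotype first becomes visible. Compared within pairs of the same number, 6 of 32 heat shock and chaperone genes and 5 of 23 Z-disc genes passed as higher in runzel, and none passed as lower. Of all tested members of these lists, 13 and 9 lay below 0. The inducible chaperone gene hspa1b rose 5.77-fold, from 363.43 ± 419.44 to 2178.0 ± 1806.7, and xirp1, which encodes an actin-binding protein of muscle attachment sites, rose 4.83-fold, from 1242.3 ± 1039.1 to 6734.2 ± 5987.4 (mean signal ± SD, n = 3). For both genes the signals of runzel and wildtype arrays overlapped, and hspa1b was dim on wildtype arrays 1 and 2, at 90.5 and 153.4. The myosin chaperone gene unc45b rose 2.64-fold, from 1759.9 ± 300.64 to 4715.1 ± 617.68. Of the epidermis markers 6 of 35 fell, and of the gut, liver and pancreas markers 7 of 36, as did skeletal actin acta1a, from 53908 ± 10698 to 31604 ± 7501.8. These calls rest on the pairing by number and on limma's intensity trend. The fit with the replicate block called 111 of 9301 probe sets, 67 higher and 44 lower, and the limma fit without the block called 0, with 447 at an unadjusted p under 0.05. Without the trend the paired fit called 3, xirp1, hspa1b and unc45b, and the calls of all other named genes were lost, acta1a (adjusted p = 0.191) among them. With the replicate number as a random block, xirp1 and hspa1b did not pass (adjusted p = 0.0791 and 0.0725), and unc45b did (adjusted p = 0.00399).

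Titin, the gene that the series title names as mutated, was represented by 4 probe sets, all of ttn.2. The brightest, at percentile 98.1 of mean signal over probe sets, read 32167 ± 11879 in runzel and 17800 ± 10002 in wildtype siblings, a log2 difference of 0.92 ± 0.416 (SD over 3 pairs), and rose in the paired limma fit (adjusted p = 0.00763) but did not pass in the unpaired fit (adjusted p = 0.977). It was higher in 3 of 3 pairs (exact sign-flip p = 0.25, exact permutation p = 0.2). It did not pass in the paired limma fit without pair 1 (adjusted p = 0.0685) or without the intensity trend (adjusted p = 0.21), nor with the random block (adjusted p = 0.201). Without wildtype replicate 1 the unpaired difference was 0.55. The second, at percentile 97.7, read 21722 ± 6616.5 and 16824 ± 9403.1, a log2 difference of 0.52 ± 0.524 that did not pass (paired adjusted p = 0.167, exact permutation p = 0.6) and turned to -0.05 without wildtype replicate 1. The other pair of titin probe sets was dim and untested in limma, at 81.2 in runzel and 84.1 in wildtype siblings (exact permutation p = 0.9) and at 23.2 and 19.9 (exact permutation p = 0.7). Where the mutation lies relative to these probes is not given in the sources used here, so titin signal does not check the genotype.

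**Figure D1:**
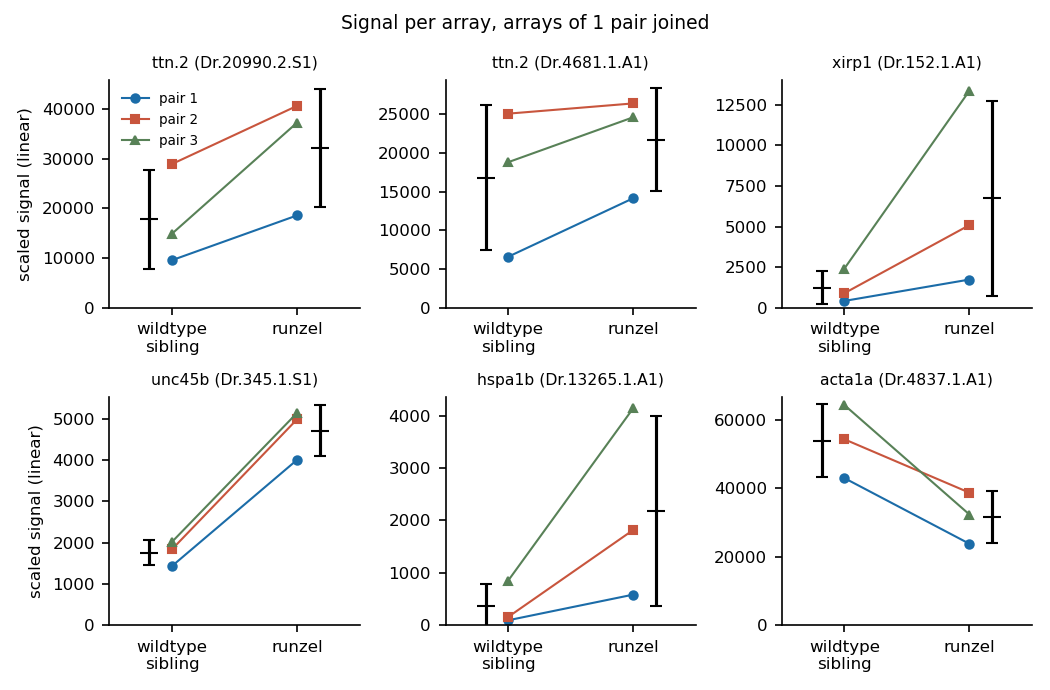
Signal of 6 probe sets (ttn.2 with its 2 bright probe sets, xirp1, unc45b, hspa1b and acta1a) on a linear axis for 3 wildtype sibling and 3 runzel arrays, with lines joining arrays of the same number and black bars giving the mean ± SD. In each panel the lines run the same way in all 3 pairs, upward to runzel except for acta1a, which fell by 0.78 on the log2 scale.

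The heat shock and chaperone list had a mean log2 change of 0.314 over 32 tested genes, with a median of 0.161, and passed camera without the block (adjusted p = 0.0035) and with it (adjusted p = 6.27e-04). The call was lost with an estimated correlation between genes (adjusted p = 0.298 unpaired and 0.352 paired). That correlation was 0.0835 unpaired and -0.0071 paired, so the paired loss does not show that these genes vary together. The unpaired call was also lost without runzel replicate 3 (adjusted p = 0.0723), without wildtype replicate 2 (adjusted p = 0.0991) and without the intensity filter (adjusted p = 0.17). In the paired fit 6 members rose and 0 fell; adjusted over the list alone, 7 rose in the paired fit and 3 in the unpaired fit. Beside hspa1b (log2 2.53 ± 0.579) and unc45b (1.40 ± 0.0645) these were the small heat shock protein genes hspb1 (1.41 ± 0.492) and hspb8 (1.26 ± 0.345), the inducible hsp70.3 (1.41 ± 0.858) and hsp90aa1.1 (0.84 ± 0.457), which encodes a chaperone of myosin folding, each higher in 3 of 3 pairs. The paired adjusted p was 4.02e-04 for hspa1b, 3.26e-04 for unc45b, 0.00234 for hspb1, 0.00161 for hspb8, 0.0445 for hsp70.3 and 0.0197 for hsp90aa1.1. With a pair left out, hsp90aa1.1 did not pass without pair 1 or pair 2 (adjusted p = 0.166 and 0.119) and hsp70.3 not without pair 2 or pair 3 (adjusted p = 0.184 and 0.241). The probe set of hsp70.3 that passed is of the kind that can cross-hybridise, so its signal may include other transcripts. None of the 6 passed without the block, where unc45b and hspb8 had the smallest adjusted p of all probe sets, 0.143.

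Genes of the Z-disc and titin-associated list had a mean log2 change of 0.221 over 23 tested genes, with a median of 0.0683. Over the 21 settings set beside the unpaired fit the mean ran from 0.123 to 0.323, and 4 of them passed. The list passed with the block (camera adjusted p = 0.00911) and not without it (adjusted p = 0.154), nor with an estimated correlation (paired adjusted p = 0.385). Under quantile normalization it passed unpaired too (adjusted p = 0.0188). In the paired fit 5 members rose and 0 fell; adjusted over the list alone, 7 rose and 2 fell. These were xirp1 (log2 2.27 ± 0.3), its relative xirp2a (0.96 ± 0.127), the filamin gene flncb (0.94 ± 0.316), desma, encoding the intermediate filament desmin (0.87 ± 0.441), and klhl41b, whose product binds nebulin (0.58 ± 0.154). Their paired adjusted p-values were 4.30e-05, 0.00338, 0.0137, 0.0106 and 0.0223, and the 5 genes were higher in 3 of 3 pairs. With the random block none of the 5 passed. Without pair 1 flncb did not pass (adjusted p = 0.108), and klhl41b not without pair 1 or pair 2 (adjusted p = 0.144 and 0.137). The M-band list of 6 genes had a mean of 0.315 and passed in both fits (camera adjusted p = 0.0372 unpaired and 0.0208 paired), but not with an estimated correlation (adjusted p = 0.298 and 0.378). Nor did it pass in the paired fit without pair 2 (adjusted p = 0.0731) or in the unpaired fit without runzel replicate 3 (adjusted p = 0.214), without wildtype replicate 2 (adjusted p = 0.139) or without the intensity filter (adjusted p = 0.0652). Of the 6 M-band genes 4 lay above 0 and 2 below, and 4 also stood in other lists. The member trim55b, which encodes a ubiquitin ligase of the M-band, rose (0.86 ± 0.29, paired adjusted p = 0.0106), but not without pair 1 or pair 2 (adjusted p = 0.0782 and 0.0741). The other members above 0 were trim55a (0.56), mybpha (0.35) and trim63b (0.30), which did not pass.

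Members of the other muscle lists moved both ways. In the fast-muscle list the myosin-binding protein C gene mybpc2b rose (log2 1.35 ± 0.418, paired adjusted p = 0.00161) and acta1a fell (-0.78 ± 0.26, paired adjusted p = 0.00313), each in 3 of 3 pairs, and 12 further members did not pass. Without pair 1 acta1a did not pass (adjusted p = 0.0527). The 5′ actin control signal was also lower in runzel, by -0.939 ± 0.251 on the log2 scale, with the 3′ signal at -0.231 ± 0.162. The fast-muscle list had a mean of 0.0652, a median of -0.0504 and a camera test pointing down, and it did not pass (adjusted p = 0.607 unpaired and 0.759 paired), but under quantile normalization its test pointed up (mean 0.15, adjusted p = 0.01 and 0.00469). Over the settings set beside the unpaired fit its mean ran from -0.00332 to 0.154. In the calcium handling list the calcium channel subunit gene cacng1a rose (0.73 ± 0.276) and the parvalbumin gene pvalb3 fell (-0.69 ± 0.253). Their paired adjusted p-values were 0.0199 and 0.017. Neither passed without pair 1 (adjusted p = 0.0966 and 0.109), and cacng1a passed with no pair left out. That list had a mean of 0.012, which turned negative under median centring, and a median of -0.105, with a camera test pointing down that did not pass (adjusted p = 0.607 and 0.696). In the dystrophin complex list, with a mean of 0.132, xirp1 rose and the caveolin gene cav1 fell (-0.57 ± 0.0737) at 2 of 4 tested probe sets, which ran to -0.0791. The dystrophin list did not pass (adjusted p = 0.393 and 0.137), except paired with a filter at the 60th percentile (adjusted p = 0.0475). Its mean ran from 0.0284 to 0.21 over the settings set beside the unpaired fit.

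Of the proteasome genes, 40 of 44 tested members lay above 0 and 4 below, with a mean log2 change of 0.179 (camera adjusted p = 3.42e-08 unpaired and 1.76e-08 paired). The call was lost with an estimated correlation (adjusted p = 0.389 and 0.352), and 0 members passed in limma at their brightest probe set in the paired fit, with 14 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone. The subunit genes psmc5 and psmd12 had log2 changes of 0.50 and 0.44 there, and a dimmer probe set of psmd12 rose (0.88 ± 0.171, paired adjusted p = 0.0253). Ubiquitin ligases and muscle-atrophy genes had a mean of 0.143 over 29 genes (camera adjusted p = 0.0399 and 0.015), with trim55b as the single member that rose and trim55a at 0.56 without passing. That call was lost with an estimated correlation (adjusted p = 0.298 and 0.352) and in the paired fit without pair 3 (adjusted p = 0.082). It was lost too in the unpaired fit without runzel replicate 2, runzel replicate 3 or wildtype replicate 2 (adjusted p = 0.0601, 0.214 and 0.0991), and unpaired without the intensity filter (adjusted p = 0.0732). The myogenic regulation and repair list had a mean of 0.237 over 19 genes (camera adjusted p = 0.00542 and 0.00433, and 0.298 and 0.352 with an estimated correlation). Its 2 passing members were the chaperone genes unc45b and hsp90aa1.1, and without the genes shared with the heat shock list it did not pass (adjusted p = 0.095 and 0.11). The full list did not pass unpaired without runzel replicate 2 (adjusted p = 0.0675), nor in either fit without the intensity filter (adjusted p = 0.165 and 0.0641). The myogenic factor gene myod1 had a log2 change of 0.89 and did not pass over all probe sets (paired adjusted p = 0.0918).

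The inflammation and acute-phase list had a mean log2 change of 0.258 over 17 genes (camera adjusted p = 0.00391 unpaired and 9.37e-04 paired, and 0.25 and 0.352 with an estimated correlation). Its member socs3b, a feedback inhibitor of cytokine signalling, rose (0.94 ± 0.222, paired adjusted p = 0.0107); adjusted over the list alone, 8 genes rose and 1 fell in the paired fit. Immediate-early and acute stress genes had a mean of 0.162 over 42 genes and passed with the block (adjusted p = 0.0308) but not without it (adjusted p = 0.067), nor with an estimated correlation (paired adjusted p = 0.352). The mean of these genes ran from 0.0789 to 0.304 over the 21 settings set beside the unpaired fit, of which 4 passed. Of these genes hspa1b and socs3b rose and the flow-responsive factor gene klf2a fell (-0.70 ± 0.172). Without the genes shared with the heat shock list the mean was 0.102 and the list did not pass (paired adjusted p = 0.117), nor did the full list without pair 1 (adjusted p = 0.132), without pair 2 (adjusted p = 0.071) or with the mean of probe sets per gene (adjusted p = 0.0521).

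Epidermis markers had the smallest p of the 30 lists in both fits, with a mean log2 change of -0.287 and 32 of 35 tested genes below 0 (camera adjusted p = 5.17e-10 unpaired and 5.57e-13 paired, and 0.298 and 0.352 with an estimated correlation). Without runzel replicate 2 the unpaired mean was -0.17 (adjusted p = 3.85e-04). In the paired fit 6 members fell and 0 rose; adjusted over the list alone, 8 fell. The keratin gene krt94 fell from 2302.3 ± 191.23 to 1068.4 ± 171.31 (-1.08 ± 0.17, paired adjusted p = 0.00447). The gene agr1, expressed in mucus-secreting cells, fell from 1411.5 ± 255.57 to 608.73 ± 61.971 (-1.14 ± 0.398, paired adjusted p = 0.0108), and krt15 (-0.97), krt17 (-0.57), krt1-19e (-0.36) and krt91 (-0.30, 1 of 2 tested probe sets) fell less far, each lower in 3 of 3 pairs. Of these 6, krt94 alone passed with each pair left out, and agr1 did not pass without pair 1 or pair 2 (adjusted p = 0.112 and 0.0741). Gut, liver and pancreas markers, which include the gut that the dissection removed, had a mean of -0.263 with 31 of 36 genes below 0 (adjusted p = 2.17e-08 and 4.63e-12, and 0.137 and 0.352 with an estimated correlation). In the paired fit 7 members fell; adjusted over the list alone, 18 fell and 1 rose. Among them were the apolipoprotein genes apoc2, from 29599 ± 2274.8 to 21149 ± 1736.1 (-0.48 ± 0.0148, paired adjusted p = 0.0106), and apoa1a (-0.33 ± 0.0206, paired adjusted p = 0.0197), the retinol carrier gene rbp4 (-0.39 ± 0.0589, paired adjusted p = 0.017) and the galectin gene lgals2b (-0.70 ± 0.237, paired adjusted p = 0.0178). None of these 4 passed without pair 1 (adjusted p = 0.155, 0.316, 0.308 and 0.0537). The intestinal phosphatase gene alpi.1 had a log2 change of -1.04 and did not pass (paired adjusted p = 0.0591).

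Endothelium markers had a mean log2 change of -0.313 over 10 genes (camera adjusted p = 0.00126 unpaired and 6.79e-04 paired, and 0.25 and 0.352 with an estimated correlation). The water channel gene aqp1a.1 (-0.60 ± 0.256, paired adjusted p = 0.0342) and klf2a (paired adjusted p = 0.0385) fell, neither passing without pair 1 (adjusted p = 0.295 and 0.181); adjusted over the list alone, 4 fell in the paired fit. Blood markers had a mean of -0.132 over 12 genes (adjusted p = 0.0372 and 0.0176, and 0.624 and 0.352 with an estimated correlation), with the embryonic globin gene hbbe2 (-0.46 ± 0.113) and aqp1a.1 lower; adjusted over the list alone, 2 rose and 5 fell in the paired fit. The list did not pass in the paired fit without pair 1 (adjusted p = 0.114). Without runzel replicate 1 or wildtype replicate 3 the unpaired mean of the blood list turned to 0.0273 and 0.0282 (adjusted p = 0.631 and 0.663). Without runzel replicate 2 and under median centring it did not pass unpaired (adjusted p = 0.0675 and 0.083). Without the intensity filter its mean was 0.0279 and it passed in neither fit (adjusted p = 0.397 and 0.239), nor with a filter at the 60th percentile (adjusted p = 0.0829 and 0.0556). Without runzel replicate 3 or wildtype replicate 1 its unpaired mean was -0.332 and -0.25.

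Oxidative phosphorylation and citric-acid cycle genes had 80 of 93 members below 0 and a mean log2 change of -0.093 (camera adjusted p = 5.76e-08 unpaired and 3.60e-07 paired, and 0.298 and 0.425 with an estimated correlation). Ribosomal protein genes had 70 of 73 below 0 and a mean of -0.0815 (adjusted p = 1.19e-09 and 2.36e-08, and 0.389 and 0.446 with an estimated correlation). In both lists 0 members passed in limma in either fit, with 16 oxidative and 8 ribosomal genes at an unadjusted p under 0.05 in the paired fit. Under quantile normalization the ribosomal mean turned to 0.0142 and the oxidative mean shrank to -0.0408 (paired adjusted p = 0.182 and 0.0713), and the unpaired ribosomal call was lost as well (adjusted p = 0.175). Without wildtype replicate 3 the unpaired ribosomal mean was -0.0419 (adjusted p = 0.00394). Without pair 3 the paired ribosomal and oxidative means were -0.0511 and -0.0605 (adjusted p = 0.00699 and 0.00765). Oxidative-stress and iron-handling genes had a mean of -0.116 over 33 genes (adjusted p = 0.00155 and 8.12e-04, and 0.298 and 0.352 with an estimated correlation), with 0 genes passing in the paired limma fit, 10 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone. Without runzel replicate 3 the unpaired mean was -0.0727 (adjusted p = 0.047). Collagens and extracellular matrix genes had a mean of -0.0414 over 42 genes and passed without the block (adjusted p = 0.0486) but not with it (adjusted p = 0.0586), nor with an estimated correlation (adjusted p = 0.624 unpaired). Of these fn1b rose (0.80 ± 0.387) and col18a1a fell (-0.51 ± 0.077), and without wildtype replicate 2 the unpaired mean of the list turned to 0.0389 (adjusted p = 0.83). The unpaired call was also lost without runzel replicate 1, runzel replicate 2 or wildtype replicate 3 (adjusted p = 0.103, 0.136 and 0.207). So it was under quantile normalization (adjusted p = 0.209), under median centring (0.0948), without the intensity filter (0.0652), with the mean of probe sets per gene (0.0801) and without the gene shared with the heat shock list (0.0564). Without wildtype replicate 1 the mean was -0.147, and the paired mean turned to 0.0456 without pair 2. A paired call appeared without pair 1 (adjusted p = 5.30e-05) and with a filter at the 60th percentile (adjusted p = 0.0331).

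The remaining lists passed in neither fit over all arrays. The paired camera adjusted p was 0.0559 for autophagy and lysosome genes (mean -0.0561), 0.0739 for p53 and apoptosis genes (0.117), 0.0782 for pigment-cell markers (-0.0983) and 0.122 for endoplasmic reticulum stress and amino-acid response genes (-0.0579). It was 0.259 for cell division (-0.04), 0.367 for circadian clock genes (-0.0448) and 0.696 for macrophage and neutrophil markers (0.075). Without pair 1, p53, cell division and notochord lists passed in the paired fit (adjusted p = 0.0108, 8.08e-04 and 0.00128), and without pair 2, autophagy and pigment lists (adjusted p = 0.0248 and 0.0437). The Z-disc, immediate-early, reticulum stress, neuron, cell division, notochord, p53 and autophagy lists each passed unpaired with some array left out. Autophagy genes passed in both fits without the intensity filter (adjusted p = 0.0335 and 0.0201), with a filter at the 60th percentile (0.0496 and 0.0475) and with the mean of probe sets per gene (0.0305 and 0.0183). With 1 array left out the neuron mean ran from -0.0952 (without wildtype replicate 1) to 0.109 (without wildtype replicate 2), the cell division mean from -0.132 (without runzel replicate 1) to 0.0651 (without runzel replicate 3) and the reticulum stress mean from -0.127 (without runzel replicate 3) to 0.0129 (without runzel replicate 2). The macrophage mean turned to -0.00226 without runzel replicate 1. Over the settings set beside the unpaired fit, the autophagy mean ran from -0.11 to -0.0154 and the p53 mean from 0.0579 to 0.148. The pigment mean ran from -0.152 to -0.0404 there. Notochord, cartilage and skeleton markers had a mean of -0.0161 and a median of 0.00976 (adjusted p = 0.679). These markers held cav1, which fell, and sox9b, which rose (0.66 ± 0.21, paired adjusted p = 0.0437) but did not pass when any pair was left out. Their unpaired mean ran from -0.135 without wildtype replicate 1 (adjusted p = 0.00105) to 0.144 without wildtype replicate 2 (adjusted p = 0.145), and was 0.0743 without runzel replicate 3. Neuron markers had a mean of 0.0216 (adjusted p = 0.665) and glia and neural progenitor markers a mean of 0.0188 with a test pointing down (adjusted p = 0.798), both turning negative under median centring. The glia mean ran from -0.0397 without wildtype replicate 1 to 0.0738 without wildtype replicate 2. Glycolysis and glycogen genes had a mean of -0.0046 (adjusted p = 0.968), which turned positive under quantile normalization and was 0.0312 without runzel replicate 1.

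**Figure D2:**
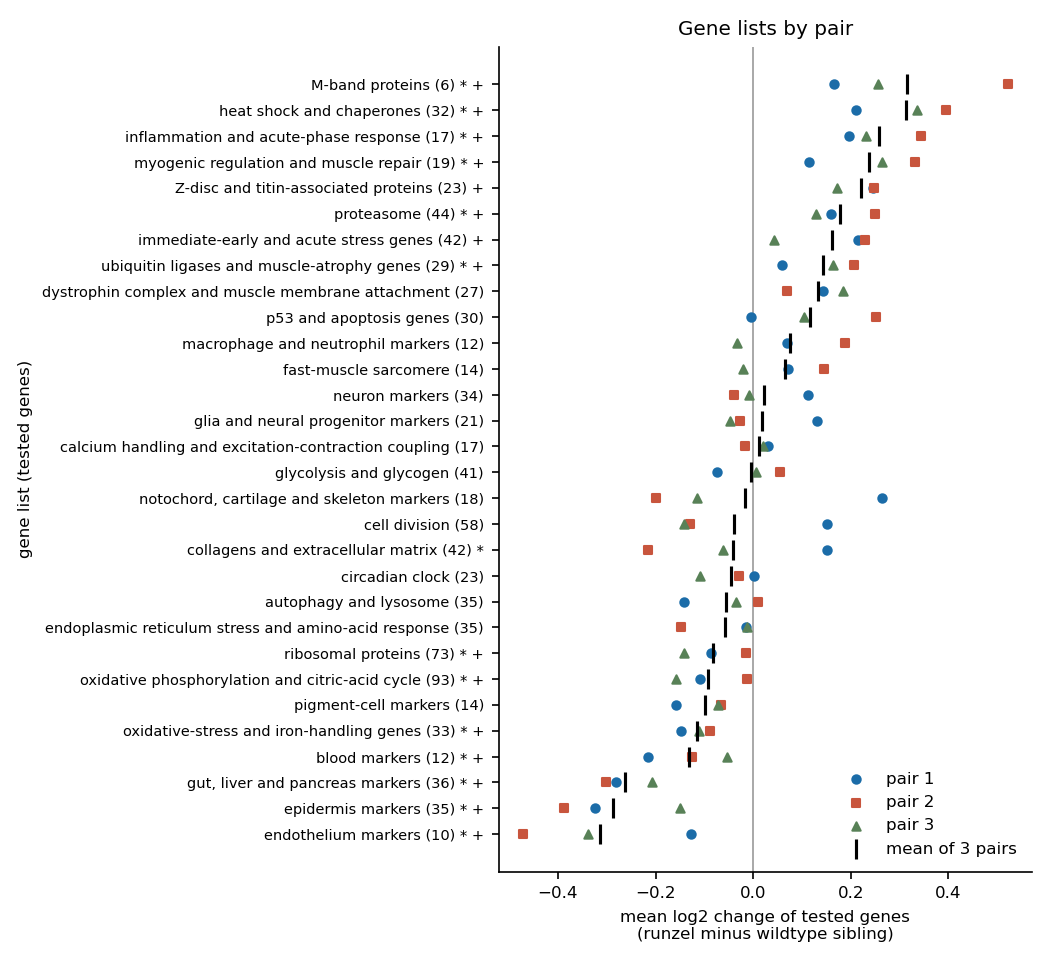
Mean log2 change (runzel minus wildtype sibling) of 30 gene lists on the horizontal axis, 1 point per pair, with the number of tested genes in parentheses. Stars and plus signs give camera calls without and with the replicate block, 14 and 15 lists, of which 13 are shared.

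Outside the lists, runzel muscle held more transcript of arpp21, from 403.33 ± 90.081 to 1290.0 ± 541.46 (log2 1.5 ± 0.505, paired adjusted p = 0.00763), and of slc16a9a, encoding a monocarboxylate transporter family member (1.38 ± 0.276, paired adjusted p = 0.00514). Also higher were mlf1 (1.3 ± 0.594), ppp1r3ca, a glycogen-targeting subunit of protein phosphatase (1.21 ± 0.273), nmrk2, a kinase of NAD synthesis in muscle (1.16 ± 0.401), and the parvalbumin gene pvalb7 (1.05 ± 0.302), with paired adjusted p-values of 0.00877, 0.00763, 0.0201 and 0.00877. The nucleophosmin gene npm1a had a log2 change of 1.16 ± 0.973 and did not pass (paired adjusted p = 0.104). The smooth-muscle genes acta2, from 8435.4 ± 1445.6 to 4330.8 ± 1420.2 (-0.99 ± 0.284, paired adjusted p = 0.00435), and tagln (-0.89 ± 0.242, paired adjusted p = 0.0113) fell. So did lxn (-1.08), tppp3 (-0.99), tm4sf4 (-0.89, 1 of 2 tested probe sets) and abcb5 (-0.75), with paired adjusted p-values of 0.0374, 0.0385, 0.0342 and 0.0253. Each of these genes had the same sign in 3 of 3 pairs, but of them only slc16a9a, mlf1, ppp1r3ca and acta2 passed with each pair left out. Without pair 2 arpp21, nmrk2, pvalb7, tagln, lxn, tm4sf4 and abcb5 did not pass in the paired limma fit (adjusted p = 0.0507, 0.0952, 0.0579, 0.0741, 0.117, 0.154 and 0.125). Without pair 1 tppp3 did not pass (adjusted p = 0.297).

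**Figure D3:**
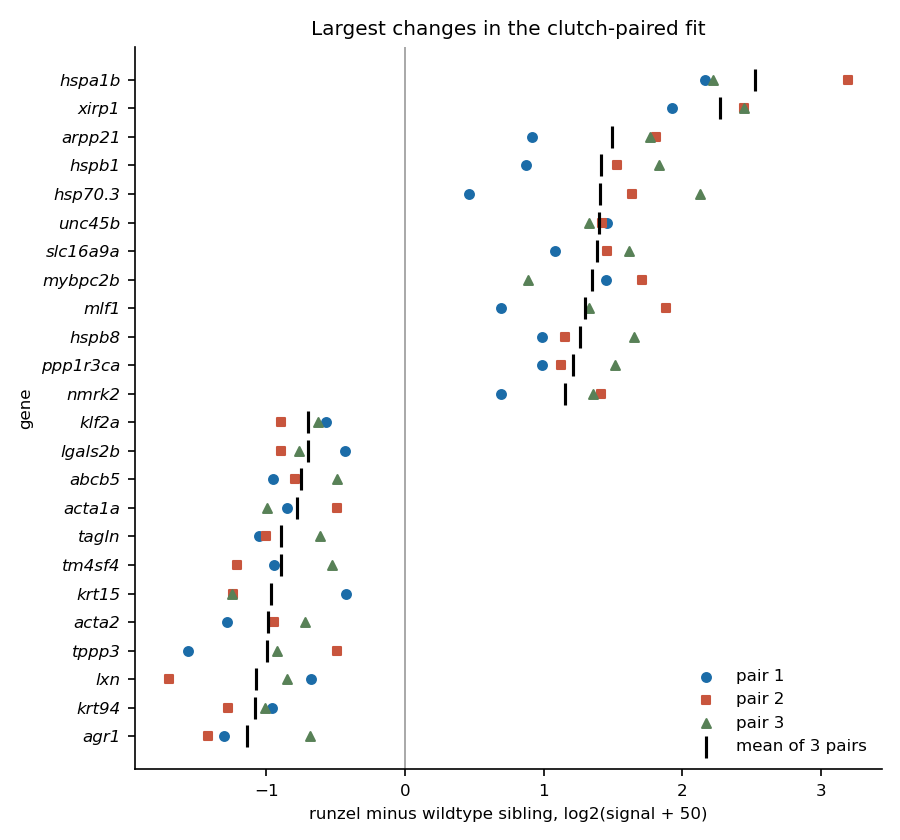
Log2 change (runzel minus wildtype sibling, log2 of signal plus 50) of 24 named genes, 1 point per pair and a tick at the mean. Means run from 2.53 for hspa1b to -1.14 for agr1.

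Without the block, limma's smallest adjusted p was 0.143, and 447 probe sets lay under an unadjusted p of 0.05, against 1181 with the block. Chance would give 465 if arrays were independent, but arrays of the same number were correlated. Other splits of the arrays that also part all pairs gave 91 to 149 without the block. Those splits are few and put any true difference between runzel and wildtype siblings into the spread within their groups. Neither 465 nor these counts is therefore a level to set 447 against. Groups did not overlap for 976 of 9301 probe sets, or 10.5%, where chance gives 10% for independent arrays. The 111 paired calls, with a median absolute log2 change of 0.769, fell to 3 without the intensity trend (xirp1, hspa1b and unc45b), to 19 with the random block, to 34 without pair 1 and to 29 without pair 2, with 149 without pair 3. Of the 111, 16 passed with each pair left out in turn, and the rest did not. Those passing were xirp1, hspa1b, unc45b, hspb1, hspb8, xirp2a, desma, mybpc2b, slc16a9a, ppp1r3ca, mlf1, krt94, acta2, rgcc, si:dkey-183i3.5 and zgc:136930. Of these, unc45b, hspb1, hspb8, ppp1r3ca, krt94, acta2, rgcc, si:dkey-183i3.5 and zgc:136930 passed with the random block. By contrast xirp1, hspa1b, xirp2a, desma, mybpc2b, slc16a9a and mlf1 did not (adjusted p = 0.0791, 0.0725, 0.0944, 0.213, 0.0559, 0.0559 and 0.0503). Only unc45b passed without the trend, with the random block and with each pair left out.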

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

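The tests of explanations in this part were chosen after the results were seen, whereas the counts over other splits of the arrays were set before the data were examined. The ratio of 3′ to 5′ actin signal on the manufacturer's control probe sets, which enter no comparison of genes, was 1.63 times as high in runzel as in wildtype siblings, and higher in 3 of 3 pairs. Breakdown of RNA would raise the GAPDH ratio as well, yet that ratio changed by -0.0667 ± 0.0596 on the log2 scale (SD over pairs) against 0.709 ± 0.159 for actin, which argues against breakdown as the whole cause. If the 5′ probe set read acta1a, both would fall alike. The 5′ signal changed by -0.939 ± 0.251 and acta1a by -0.78 ± 0.26, a gap of -0.16 ± 0.0693. The spread over pairs does not measure how far 2 probe sets of 1 transcript differ in response. This gap therefore cannot decide whether the fall of acta1a accounts for the 5′ signal. The middle actin control read 111729, 130395 and 123612 on runzel arrays 1 to 3 and 119488, 126501 and 146478 on wildtype arrays 1 to 3. In pair 2 it was higher in runzel. The 3′ and middle signals, 103870 to 167537, lay near the arrays' largest signals outside the controls, 124249 to 173549. How far such bright probe sets can register a fall was not tested. Open and untested are also a change in actin transcripts with the runzel genotype and which transcripts the 5′ probes bind.

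Transcripts of 6 chaperone genes that passed with the replicate block were higher in runzel, by a mean log2 change of 1.48 ± 0.295. These genes were picked because they passed, and the whole heat shock list of 32 genes, with a mean of 0.314, lost its call with an estimated correlation (adjusted p = 0.352 paired). That paired test has only 2 residual degrees of freedom. A larger share of muscle would raise fast-muscle sarcomere genes alike; the heat shock list exceeded them by 0.249 ± 0.109 as deposited and by 0.15 ± 0.0885 under quantile normalization, too close to the spread over pairs to exclude it. Acute handling stress before lysis would raise immediate-early genes, and that list without shared heat shock genes had a mean change of 0.102 ± 0.103, with 0.171, 0.151 and -0.016 in the 3 pairs. Handling, muscle share and genotype cannot be told apart from these values, with 3 pairs and an immediate-early change uneven between them, and a response to the runzel genotype stays open and untested.

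Lists of epidermis, gut and liver, endothelium and blood markers passed as lower in runzel with a preset correlation, and none passed with an estimated one (paired adjusted p = 0.352 for each); the blood call was also lost in the paired fit without pair 1 (adjusted p = 0.114) and without the intensity filter (adjusted p = 0.239). A smaller share of every tissue other than muscle would lower neuron markers as much. These lay above the mean of the 4 lists by 0.27 ± 0.0869 (0.35, 0.283 and 0.178 in the 3 pairs). The 4 lists were picked because they passed as lower, which favours such a gap, so it cannot decide the question. Neuron markers themselves had means of 0.113, -0.0391 and -0.00919 in the 3 pairs, and of -0.0952 unpaired without wildtype replicate 1. Less gut and liver tissue carried over in dissection would lower all of that list's brightest genes, and 8 of the 10 brightest were lower in all 3 pairs (median -0.365), with apoeb at -0.02 and apobb.1 at -0.17 as exceptions. A smaller share of epidermis would do the same there, and 9 of 10 were lower in all 3 pairs (median -0.187), with perp as the exception. Here too the lists were picked because they passed as lower, with 31 of 36 gut and liver and 32 of 35 epidermis genes below 0. High counts among their brightest genes were thus favoured in advance and cannot decide the question. Tissue shares and expression within these tissues cannot be told apart without a measure of tissue content, and an effect of the runzel genotype stays open and untested.

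For the count of probe sets passing without the block, the 6 arrays make 10 splits, and all 10 gave 0 calls, the real one and the highest other alike. At an unadjusted p under 0.05 the real split gave 447, the other 3 splits that part all pairs gave 91 to 149, and the 6 splits that part 1 pair gave 441 to 1004, a structure of the samples by replicate number. Swapping groups within pairs makes 4 splits, of which 1, the real one, gave as many as 111 calls, and the highest other gave 0. For gene lists without the block, 2 of 10 splits gave as many as the real 14, and the highest other, also 14, parts 1 pair only. With the block 1 of 4 splits gave as many lists as the real 15, and the highest other gave 10. These splits are too few for a share under 0.05.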

How the results depend on the processing

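The settings run in the paired fit, the random block, pairs left out and lists without shared genes were chosen after the data were seen. Each gene of the naming rule other than titin kept its direction under every setting run. Without the replicate block limma called 0 probe sets, except for 111 with the block, 19 with the number as a random block, and a range of 0 to 1 over arrays left out (1 without runzel replicate 1). Titin probe sets passing rose from 0 to 1 with the block. The 14 lists called without the block became 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 with fry (4) and 9 without the filter. In the paired fit the 111 calls became 3 without the intensity trend, 0 without the block, 19 with the random block, and 29 to 149 with a pair left out; quantile normalization gave 69 higher and 34 lower, and median centring 46 and 47, against 67 and 44. The paired titin count of 1 became 0 without the trend, without the block and with the random block, and 0 to 1 with a pair left out. The 15 paired lists became 0 with an estimated correlation (2) and 0 with fry (8). The block added the Z-disc and immediate-early lists, removed the collagen list and changed no other list call. Under quantile normalization the fast-muscle sarcomere mean was 0.1541 with the test reversed in both fits, and the ribosomal mean turned to 0.01422 in both; the neuron mean ran from -0.0952 (without wildtype replicate 1, reversed) to 0.109 (without wildtype replicate 2) over arrays left out. By its construction the test with an estimated correlation uses only 4 residual degrees of freedom, or 2 with the block, and leaving out arrays leaves fewer samples. Estimated correlations also lay far above the preset 0.01 in some lists. Unpaired and paired they were 0.41 and 0.184 for epidermis, 0.407 and 0.411 for ribosomal, and 0.392 and 0.0988 for proteasome genes. For the heat shock list they were 0.0835 and -0.0071. For the inflammation list they lay under the preset in both fits, at -0.0276 and -0.00215. The lost call of that list thus came without a raised correlation. Where genes vary together, camera at the preset gives p-values that are too small. The cause of the other changes was not tested. Dim probe sets, among them a pair for titin, lie too near background to compare.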

Other observations

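The genes named in this part were chosen after the results were seen. Outside the lists, 2 transcripts known only by clone names fell far in the paired limma fit, one of them further than any other called probe set. They were si:dkey-183i3.5, from 37690 ± 8147.5 to 14858 ± 6496.3 (log2 -1.40 ± 0.288, paired adjusted p = 1.16e-04), and zgc:136930, from 31875 ± 6442.3 to 15159 ± 4955.8 (-1.10 ± 0.33, paired adjusted p = 0.00122), each lower in 3 of 3 pairs. Both were bright in wildtype siblings and both passed with each pair left out, but not without the intensity trend (adjusted p = 0.0754 and 0.128).

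Higher in runzel in 3 of 3 pairs were eef2k, the kinase of elongation factor 2 (log2 0.77 ± 0.267, paired adjusted p = 0.0103), and nexn, encoding the Z-disc protein nexilin (0.70 ± 0.13, paired adjusted p = 0.017). The gene tent5c, encoding a poly(A) polymerase, rose at 2 of 4 tested probe sets (0.75 and 0.65, paired adjusted p = 0.0197 for both). The mitochondrial protein gene higd1a rose at 1 of 2 (0.84 ± 0.204, paired adjusted p = 0.0106), and clu, which encodes the extracellular chaperone clusterin, rose by 0.88 ± 0.256 (paired adjusted p = 0.019). The cell-cycle regulator gene rgcc rose by 0.96 ± 0.347 (paired adjusted p = 0.00514). None of these genes passed without the block or without the intensity trend, and rgcc alone passed with each pair left out.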
